A study of Homo sapiens with 3 samples.

How the data were processed

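RNA was measured by sequencing in 3 libraries of Hep-G2, an established human cell line derived from a hepatoma. One library came from cells carrying a control shRNA, and the other 2 came from cells carrying a short hairpin RNA (shRNA) against FTO, here called sh#2 and sh#7 after the labels. Per the labels, all 3 cultures were at passage 21, total RNA was extracted and treated with DNase, and libraries followed a standard Illumina protocol. Each group held 1 library, so nothing in these data measures the spread between cultures.

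The authors deposited a single table of FPKM values (fragments per kilobase of transcript, scaled to the mapped total), with 1 row per gene and 1 column per library. Per the submitters' processing notes, STAR 2.4.0j, HTSeq and Cufflinks 2.2.1 were used with the human genome build hg19; which of them made which step is not given in the sources used here. The table lists 21572 gene symbols with no repeated symbol. In it, 26 symbols had been turned into calendar dates by a spreadsheet, and those genes were kept under the altered names and not named. Mitochondrially encoded genes were not analysed here. FPKM divides by the total, so a few abundant genes can shift all others: the 100 highest genes held 34.7% of all FPKM in the control, 31.3% in sh#2 and 29.0% in sh#7.

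FPKM values are not counts, so no count model was used. Differences were computed as log2(FPKM + 1) of 1 library minus log2(FPKM + 1) of another, which understates the change of low genes. Genes with a mean of at least 1 FPKM over the 3 libraries were compared, which left 11069. A gene was counted as higher or lower where the difference reached 2-fold on that scale. These counts describe sizes in these libraries and are no test. The median difference of the compared genes was 0.16 for sh#7 against control, 0.10 for sh#2 against control and 0.05 for sh#7 against sh#2, and list medians are given relative to it.

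The depth was estimated from low values. Ratios of low genes between libraries gather at steps that mark single fragments, and these put the depth of sh#2 at 1.02 and that of sh#7 at 0.992 times the control. Genes with a single annotated transcript longer than 800 nt in GENCODE 29 put 1 fragment at a level that corresponds to about 42.9 M (mega) fragments in the control, 44.0 M in sh#2 and 42.5 M in sh#7. These are approximate, since transcript lengths came from a newer annotation than the authors' build. Intervals beside a value are exact (Clopper-Pearson) 95% intervals on estimated fragments and cover counting error only.

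A set of 34 gene lists was fixed before the data were examined. Of these, 31 had at least 5 members among the compared genes. For each, the median difference was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was said to stand apart at or below the 2.5 or at or above the 97.5 percentile. The percentile describes these libraries and is not a p-value. The lists that could not be placed were endothelial markers with 2 compared members, neural and kidney markers with 3, and mitochondrially encoded mRNAs with 0. Chance gives about 1.55 lists per line.

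Genes were named by a rule fixed at the same time. It took FTO; the 12 genes in each direction with the largest smaller difference among those past 2-fold in both lines; the 4 genes in each direction with the largest difference in each comparison, all with a mean of at least 5 FPKM; the 4 members with the largest mean difference of each list that stood apart or held a member past 2-fold in both lines; and any compared member of the m6A list or of the list of genes next to FTO. Genes named outside it are marked as such.

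Both lines were compared with the same control library. The overlap and the correlation were therefore set beside 20 simulated sets of unchanged libraries with counting noise alone, over 10817 genes with an estimated fragment number, and beside the overlap of independent lists. The single control library cannot be split. The share of genes ordered control, sh#2, sh#7 was set beside 10000 draws of sh#2 differences from all compared genes, a comparison added after the data were seen. Runs of neighbouring genes, a search added after the data were seen, were sought in windows of 21 compared genes ordered along the autosomes and X in RefSeq on GRCh38.p14, used for order only. A window was kept when its median passed the largest window median of 95 of 100 shuffles of gene order. GC content and transcript length came from GENCODE 29 and covered 97.7% of the compared genes.

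The calculations were tested on simulated data first. For sh#7 against control, with 10817 genes, 97.0% of 66 genes changed 4-fold and 82.1% of 67 genes changed 2.5-fold passed the 2-fold threshold in the right direction, and 0 of 10617 unchanged genes passed it. These simulated libraries hold counting noise only, so they do not measure false calls from differences between cultures. Of 500 random lists, 4.4% stood apart. A planted run of 60 genes, shifted by -0.6 on the log2 scale, was recovered in full, and no run was called in shuffled genes. Smaller shifts and shorter runs were not planted. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a minimum mean of 5, median-of-ratios and upper-quartile scaling, a 1.5-fold threshold, the mean in place of the list median, and another treatment of repeated symbols. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.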

Results

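Gene expression was compared in Hep-G2 hepatoma cells carrying a control shRNA and in 2 lines carrying different shRNAs against FTO, which encodes an RNA demethylase that removes N6-methyladenosine (m6A). The series design describes the knockdown as more efficient in sh#7 than in sh#2. Each line gave 1 library of about 42.5 to 44.0 M estimated fragments, so no difference below has a replicate check and an effect of FTO cannot be separated from an effect of a line. A total of 11069 genes were compared.

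FTO was measured at 9.02 FPKM in the control, 5.29 FPKM in sh#2 and 2.55 FPKM in sh#7. Its level was 58.6% of the control in sh#2 (95% interval 51.4 to 66.6) and 28.2% in sh#7 (23.7 to 33.3), where the intervals cover counting error only. The order of the libraries follows their labels. On the log2(FPKM + 1) scale the difference was -0.67 in sh#2 and -1.50 in sh#7.

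In sh#7, several plasma protein genes of the hepatocyte were far below the control. Of 33 compared hepatocyte secreted protein genes, 14 were past 2-fold lower and 1 was past 2-fold higher. Of 15 acute phase genes, 8 were lower and 1 was higher by that measure. AFP, which encodes the fetal plasma protein alpha-fetoprotein, was at 961 FPKM in the control and 15.7 FPKM in sh#7. The fibrinogen chain genes FGA, FGB and FGG were at 260, 28.6 and 419.6 FPKM in the control and at 3.96, 0.662 and 10.6 FPKM in sh#7. BPIFB2 was at 98.5 and 2.08 FPKM. The highest genes relative to the control were NPNT, RBPMS2, GPR56 and SLC30A3, of which the first 3 differed by 3.34, 3.30 and 3.12 on the log2 scale and SLC30A3 was at 1.62 and 19.9 FPKM. In all, 260 genes were higher and 275 were lower in sh#7 by at least 2-fold; the 260 became 394 with a pseudocount of 0.1 and 146 at a minimum mean of 5 FPKM. Higher genes made up 48.6% of these, against 33.4% after median-of-ratios scaling and 38.5% after upper-quartile scaling.

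In sh#2, the genes furthest below the control were IGFBP1, C10orf10 and CYP2S1. IGFBP1, a binding protein of insulin-like growth factors, was at 1361 FPKM in the control and 175 FPKM in sh#2. C10orf10 was at 55.3 and 10.6 FPKM and CYP2S1 at 11.4 and 1.78 FPKM. HULC, a long non-coding RNA first described in liver cancer, was at 4.39 FPKM in the control, 48.0 FPKM in sh#2 and 3.79 FPKM in sh#7. A pair of short RNAs was also picked by size: SCARNA22 was at 20.5 FPKM in the control and listed at 0 in both knockdown lines. VTRNA1-2 was at 75.2 FPKM in sh#2 and listed at 0 in the others. No counting interval was available for either, so how many fragments lie behind these values is not known. Fewer genes passed 2-fold than in sh#7, with 56 higher and 80 lower, which became 106 and 138 with a pseudocount of 0.1 and 24 and 49 at a minimum mean of 5 FPKM. Higher genes made up 41.2%, against 30.7% after median-of-ratios scaling and 32.9% after upper-quartile scaling.

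**Figure D1:**
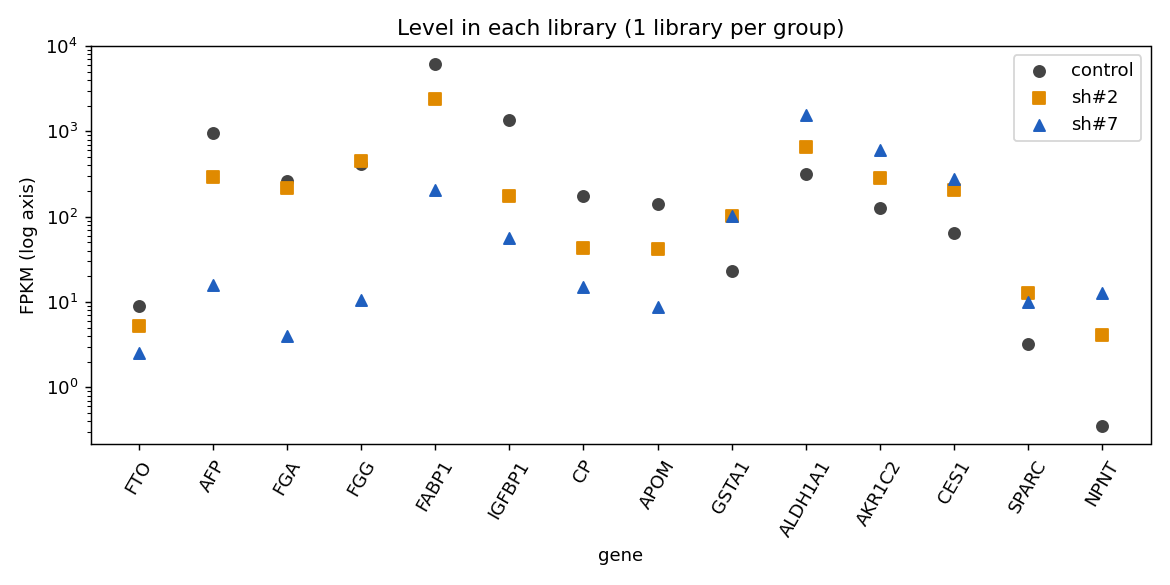
FPKM (log axis) of selected genes in the control (circles), sh#2 (squares) and sh#7 (triangles), with 1 library per point. AFP was at 961, 294 and 15.7 FPKM in the control, sh#2 and sh#7, while GSTA1 was at 23.4, 101 and 103 FPKM.

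The genes highest in both lines by the fixed rule included several enzymes. GSTA1, a glutathione transferase, was at 23.4 FPKM in the control, 101 FPKM in sh#2 and 103 FPKM in sh#7, and GSTA2 was at 1.24, 5.86 and 15.6 FPKM. The retinal dehydrogenase gene ALDH1A1 was at 319.6, 658 and 1560 FPKM, and the aldo-keto reductase gene AKR1C2 at 126, 286 and 602 FPKM. CES1, a liver carboxylesterase, was at 65.1, 207 and 277 FPKM. ACSL1 and ACSS1, which activate fatty acids and acetate, were at 10.5 and 12.1 FPKM in the control, 25.9 and 30.2 FPKM in sh#2, and 26.5 and 38.4 FPKM in sh#7. The other genes named by size were NPNT, SPARC, ZNF114, FSCN1 and ZBED3. GSTA1 and GSTA2, and AKR1C1 and AKR1C2, are near-identical pairs, and how reads were divided within each pair is uncertain.

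The genes lowest in both lines by the same rule included IGFBP1, PLA2G2A, CP, APOM and AFP. IGFBP1 was at 1361 FPKM in the control, 175 FPKM in sh#2 and 57.0 FPKM in sh#7. FABP1, the liver fatty acid binding protein and a member of the PPARA target list, was at 6167, 2415 and 208 FPKM. The secreted phospholipase gene PLA2G2A was at 517, 117 and 56.9 FPKM, the ceruloplasmin gene CP at 175, 43.1 and 14.9 FPKM, and the apolipoprotein gene APOM at 140.2, 41.5 and 8.70 FPKM. TM4SF5 and CTDSPL were lower by almost the same amount in both lines, with log2 differences of -1.57 and -1.54 in sh#2 and -1.56 and -1.55 in sh#7. FILIP1L and ISM2 were also among the 12.

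Together, 28 genes were higher and 58 were lower in both lines, where independent lists of these sizes would share 1.32 and 1.99. The 28 became 71 with a pseudocount of 0.1 and 12 at a minimum mean of 5 FPKM, and the 58 became 33 at that minimum. No simulated set of unchanged libraries shared a gene in either direction. At most 1 simulated gene per set passed 2-fold in sh#7, so there was almost nothing to share. These sets show only that counting noise alone rarely gives such calls. The log2 differences of the lines correlated across genes with r = 0.55, against 0.50 in the simulated sets; genes are not independent replicates. The covariance was 0.0901, against 0.00402 in the simulated sets. The simulation holds counting noise only, so part of the excess may come from the shared control culture. Of the 535 genes past 2-fold in sh#7, 438 (81.9%, exact 95% interval 78.3 to 85.0) had an sh#2 level between those of the control and sh#7. With sh#2 differences drawn at random from all compared genes the share averaged 49.2%, and the highest of 10000 draws was 57.0%. The shared control also favours such an order, as does choosing genes by their sh#7 difference, so the share cannot be tied to the level of FTO. Of the 136 genes past 2-fold in sh#2, 65 differed from the control in the same direction and by more in sh#7.

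**Figure D2:**
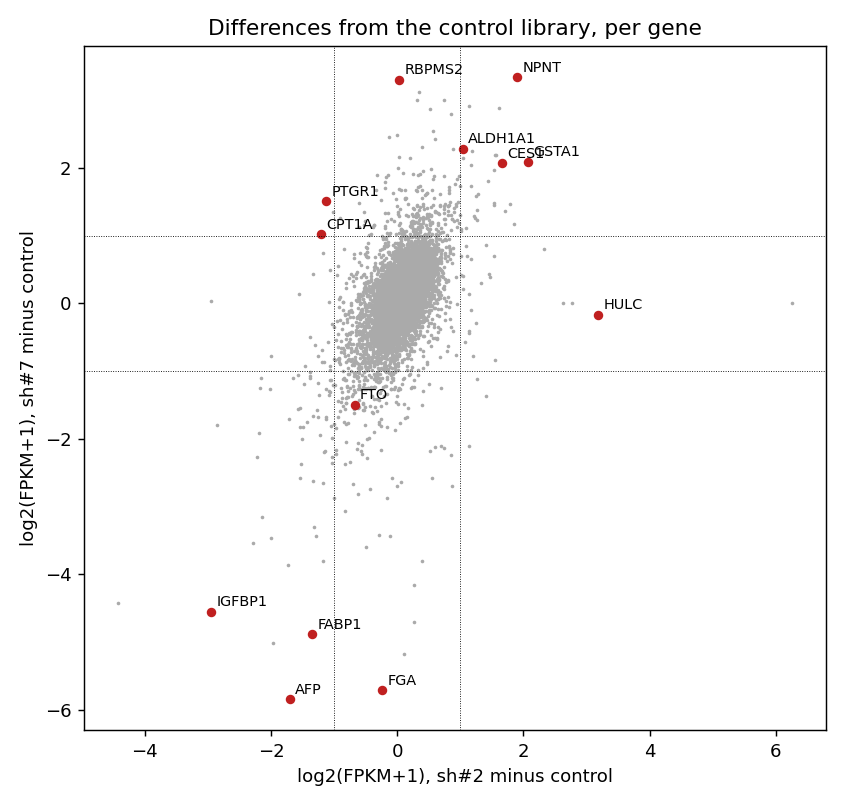
Difference from the control on the log2(FPKM + 1) scale in sh#2 (x axis) and sh#7 (y axis), 1 point per compared gene, with dotted lines at 2-fold. IGFBP1, AFP and FABP1 lie below -1 on both axes and GSTA1 and CES1 above 1 on both, while CPT1A and PTGR1 lie on opposite sides.

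Compared with each other, the knockdown lines differed by at least 2-fold in 161 genes that were higher and 168 that were lower in sh#7; the 161 became 252 with a pseudocount of 0.1 and 82 at a minimum mean of 5 FPKM. FGA was at 219 FPKM in sh#2 and 3.96 FPKM in sh#7, FGG at 454 and 10.6 FPKM, and TNNI2, a troponin subunit, at 227 and 6.27 FPKM. PTGR1, a prostaglandin reductase, was at 13.0 FPKM in sh#2 and 86.0 FPKM in sh#7, and RBPMS2 at 1.22 and 20.5 FPKM. GPR56 and SLC30A3 were at 2.82 and 2.25 FPKM in sh#2 and at 25.0 and 19.9 FPKM in sh#7.

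Among hepatocyte secreted protein genes, 30 of 33 in sh#7 and 28 of 33 in sh#2 lay below the median of all genes. Relative to the median of all genes, the list median was -1.01 in sh#7 and -0.33 in sh#2 on the log2 scale, in each case below all random lists. TTR, the carrier of thyroxine and retinol-binding protein, was at 61.1 FPKM in the control, 26.6 FPKM in sh#2 and 3.43 FPKM in sh#7, and the fetuin gene AHSG was at 4399, 2005 and 1353 FPKM. Acute phase genes stood apart in sh#7 with a relative median of -1.62, and lay at -0.11 in sh#2 (percentile 17.4). Hepatocyte transcription factors stood apart in neither line, at -0.07 and 0.04 in sh#7 and sh#2. Without a filter on low values they did stand apart in sh#7, at a relative median of -0.07.

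Glycolysis and hypoxia genes were lower in both lines: 28 of 29 members in sh#7 and 29 of 29 in sh#2 lay below the median of all genes. The relative list median was -0.97 in sh#7 and -0.61 in sh#2, below all random lists. The glucose transporter gene SLC2A1 was at 228 FPKM in the control, 118 FPKM in sh#2 and 83.4 FPKM in sh#7. BNIP3, a mitophagy receptor induced by hypoxia, was at 273, 139 and 75.2 FPKM, P4HA1 at 95.3, 53.9 and 33.6 FPKM, and EGLN3 at 5.66, 2.07 and 1.77 FPKM.

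Fatty acid oxidation and PPARA target genes had relative medians of -0.44 in sh#7 and -0.25 in sh#2, with TXNIP at 37.5, 20.8 and 6.47 FPKM and PLIN2, a lipid droplet protein, at 331, 193 and 134 FPKM in the control, sh#2 and sh#7. Immediate early genes lay at -0.30 and -0.25, with DUSP6 at 54.0, 20.9 and 7.90 FPKM. Cytosolic ribosomal protein genes lay at -0.38 and -0.18, with 62 and 53 of 63 members below the median of all genes, but by the mean of members (-0.33 and -0.13) the list stood apart in neither line. Gluconeogenesis and insulin signalling genes stood apart in sh#2 (-0.18, percentile 0.38) and were at -0.17 in sh#7 (percentile 3.71). In sh#7 this list did stand apart without a filter (-0.13), with GC content and length corrected (-0.27) and by the mean of members (-0.63). Endoplasmic reticulum chaperones stood apart in sh#7 at -0.41, and lay at -0.13 in sh#2 (percentile 8.86). Placed directly for sh#7 against sh#2, relative medians were -1.49 for acute phase genes (percentile 0) and -0.14 for gluconeogenesis and insulin signalling genes (percentile 2.39), while endoplasmic reticulum chaperones, at -0.14 (percentile 12.6), did not stand apart. Immediate early genes in sh#7 and gluconeogenesis genes in sh#2 no longer stood apart at a minimum mean of 5 FPKM, nor immediate early genes in sh#7 without a filter, nor chaperones in sh#7 by the mean of members.

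Several lists were higher. NRF2 target genes lay at 0.32 in sh#7 and 0.10 in sh#2, with the aldo-keto reductase gene AKR1B10 at 40.2, 61.8 and 106 FPKM in the control, sh#2 and sh#7. S phase and E2F target genes lay at 0.30 and 0.14, with the replication genes MCM4 at 31.0, 47.8 and 54.8 FPKM and MCM2 at 50.9, 69.7 and 84.6 FPKM. p53 target genes lay at 0.24 and 0.20, with CDKN1A, a cell cycle inhibitor, at 43.8, 57.9 and 96.7 FPKM and FDXR at 46.5, 80.8 and 95.1 FPKM. Wnt and beta-catenin targets stood apart in sh#7 at 0.56, with CCND1 at 91.7, 128 and 287 FPKM and AXIN2 at 26.4, 31.4 and 59.5 FPKM. In sh#2 these targets lay at 0.10 (percentile 95.65). They did stand apart there with GC content and length corrected (0.12) and by the mean of members (0.20). Metallothioneins and replication-dependent histones, families of near-identical genes, also stood apart in sh#7, at 0.37 and 0.34. In sh#2 they lay at 0.15 and 0.15 (percentiles 96.48 and 97.47). Histones in sh#2 did stand apart with a pseudocount of 0.1, under both scalings and without the runs of genes lower in sh#7. ATF4 and amino acid response genes (0.15) and the RNA interference machinery (0.16) stood apart in sh#2. In sh#7 these lists lay at 0.03 and 0.16 (percentiles 78.6 and 91.1). Placed directly for sh#7 against sh#2, neither stood apart (percentiles 5.12 and 43.1). Calls lost under an alternative were those of p53 and NRF2 targets and the RNA interference machinery in sh#2 at a minimum mean of 5 FPKM, of NRF2 targets in sh#2 without the runs of genes lower in sh#7, of the machinery with GC content and length corrected or by the mean of members, and of histones in sh#7 under median-of-ratios scaling or by the mean.

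**Figure D3:**
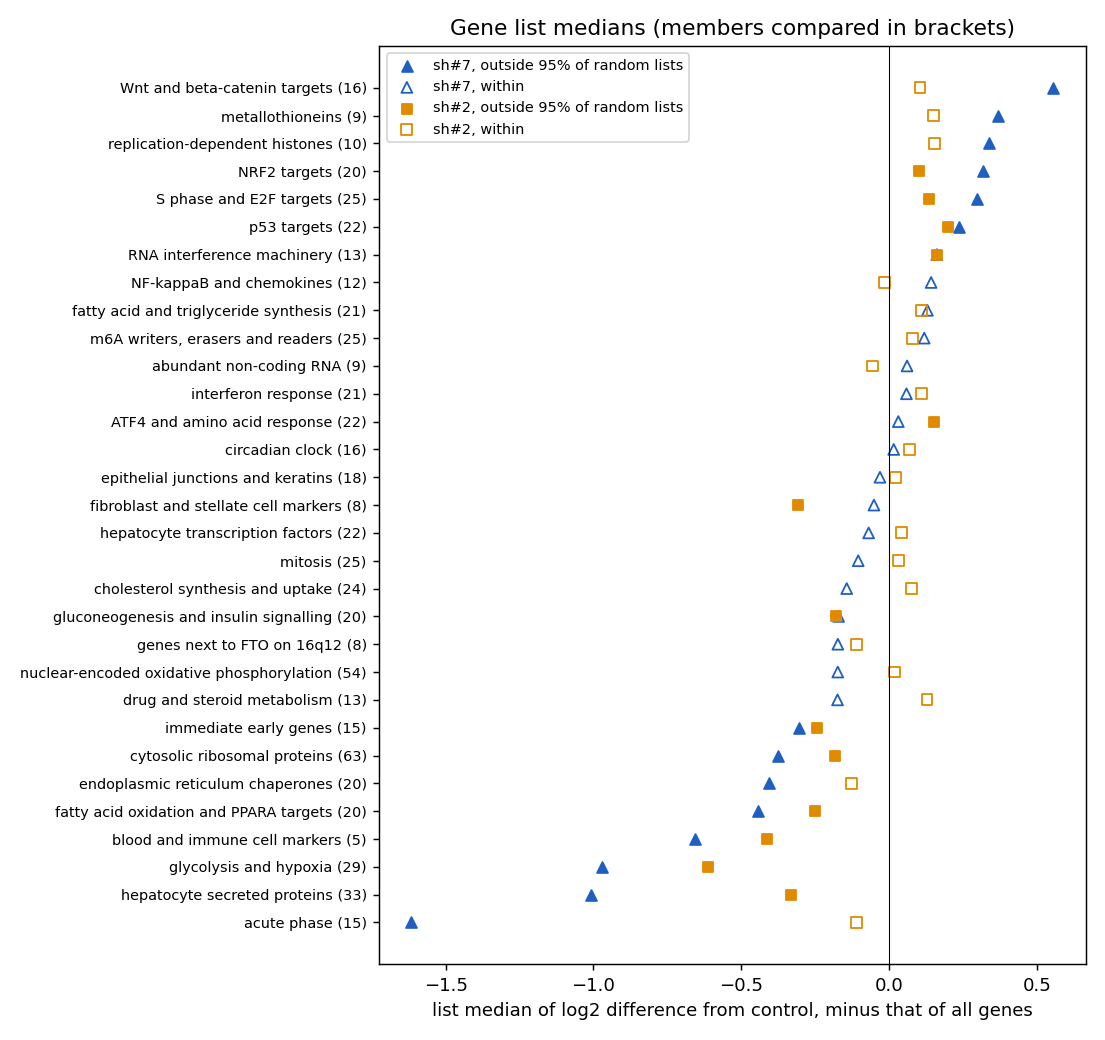
Median log2(FPKM + 1) difference from the control of each gene list, minus the median of all genes, in sh#7 (triangles) and sh#2 (squares), with filled marks outside 95% of random lists. The secreted protein list lies at -1.01 in sh#7 and -0.33 in sh#2, and the Wnt list at 0.56 and 0.10.

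Genes of the m6A machinery other than FTO stayed within 2-fold of the control. No member of the 25 in that list passed 2-fold in either line, and the relative list median was 0.12 in sh#7 and 0.08 in sh#2, within the range of random lists. At a minimum mean of 5 FPKM the list did stand apart in sh#7, at 0.15. METTL3, the catalytic subunit of the m6A writer, was at 40.2 FPKM in the control, 41.6 FPKM in sh#2 and 32.1 FPKM in sh#7, and its partner METTL14 was at 10.1, 13.5 and 15.1 FPKM. ALKBH5, the other m6A demethylase, was at 36.4, 34.1 and 37.1 FPKM. Among 8 compared genes next to FTO on chromosome 16, CES1 was past 2-fold higher in both lines, at 65.1, 207 and 277 FPKM, and TOX3 was past 2-fold lower in sh#7, at 15.7, 8.58 and 5.37 FPKM. IRX3 was at 42.8, 37.3 and 22.4 FPKM and RPGRIP1L, which adjoins FTO, was at 2.66, 2.60 and 3.13 FPKM.

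Markers of other cell types were checked as well. The 5 compared blood and immune markers lay at -0.65 in sh#7 and -0.41 in sh#2, led by the lysozyme gene LYZ, at 3216 FPKM in the control, 1321 FPKM in sh#2 and 297 FPKM in sh#7. The 8 compared fibroblast and stellate cell markers went both ways and stood apart in sh#2 at -0.31, a median that turned to 0.031 at a minimum mean of 5 FPKM and no longer stood apart without a filter or by the mean of members, with LOX at 42.7, 17.1 and 13.7 FPKM and SPARC at 3.22, 12.8 and 9.87 FPKM.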

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

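In 6 genes the lines moved past 2-fold in opposite directions from the control, a difference that was not tested, and all but PTGR1 were chosen after their values were seen. CPT1A, which carries fatty acids into mitochondria, differed from the control by 1.02 in sh#7 and -1.21 in sh#2 on the log2 scale. CDH2, which encodes N-cadherin, differed by 1.35 and -1.01, and PTGR1 by 1.51 and -1.12. The amino acid transporter gene SLC6A14 differed by -2.11 in sh#7 and 1.13 in sh#2, MAP7D2 by -1.12 and 1.27, and ATP10D by -1.37 and 1.41. These 6 genes do not follow the order of FTO in the 3 libraries.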

How the results depend on the processing

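Alternatives added after seeing the data were a GC and length correction, leaving out genes of the runs, and leaving out short RNAs and genes listed at 0. No paired analysis was possible because each group holds 1 library, and leaving out replicates was impossible for the same reason. The correlation of the lines and the FTO differences kept their sign under every alternative run. A pseudocount of 0.1 gave 394 genes higher in sh#7 than control, 106 higher and 138 lower in sh#2, 252 higher in sh#7 than sh#2, and 71 higher in both lines. A minimum mean of 5 gave 146, 24, 49, 82 and 12 for these, and 33 lower in both, since fewer genes were compared. At 1.5-fold the counts were 1064 higher and 684 lower in sh#7, 295 and 301 in sh#2, 569 and 504 in sh#7 against sh#2, and 167 and 194 in both lines. FTO in sh#7 was at -1.78 with the pseudocount of 0.1, which follows from its low level, and at -1.69 with GC and length corrected, where its annotated transcript may be longer than the authors' model. The other 105 summary values stayed within 1.5 times or within their interval; no symbol was repeated, so that setting moved nothing. Of 614 list values, 572 kept their call, 25 newly stood apart, 16 no longer did, and 1 that had stood apart changed sign. That was fibroblast markers in sh#2, from -0.31 to 0.031 at a minimum mean of 5, and the cause was not tested. Some values that newly stood apart at that minimum also changed sign. Circadian clock genes went from 0.02 to -0.52 in sh#7 and from 0.07 to -0.36 in sh#2. Fibroblast markers in sh#7 went from -0.05 to 0.60. Of 1108 values of named genes, 369 were counted as moved, 172 of them under median-of-ratios and 128 under upper-quartile scaling, and 0 of those past 2-fold changed sign. A value counted as moved where it fell outside its counting interval or had none. SCARNA22, VTRNA1-2 and HULC had no interval, so their values count as moved whatever their size. Ribosomal protein genes stood apart in neither line by the mean of members (-0.33 and -0.13). Counting depth limits the low genes most.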

Other observations

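The placements of gene lists in this part were fixed beforehand. The other tests were added after the data were seen. Of these, those of GC content and transcript length were set before the corrected values were seen. The rest were set after the values they use or closely related ones.

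Lists that stood apart in neither line had these relative medians in sh#7 and sh#2: cholesterol synthesis and uptake -0.14 and 0.07, fatty acid and triglyceride synthesis 0.13 and 0.11, mitosis -0.10 and 0.03, interferon response 0.06 and 0.11, NF-kappaB and chemokines 0.14 and -0.02, drug and steroid metabolism -0.17 and 0.13, circadian clock 0.02 and 0.07, epithelial junctions and keratins -0.03 and 0.02, nuclear-encoded oxidative phosphorylation -0.17 and 0.02, abundant non-coding RNA 0.06 and -0.05, and genes next to FTO -0.17 and -0.11. Within them, the triglyceride synthesis gene GPAM was at 9.48 FPKM in the control, 17.4 FPKM in sh#2 and 32.4 FPKM in sh#7, while ACSL4 was at 162, 111 and 68.1 FPKM. UGT1A1, which conjugates bilirubin, was at 7.87, 4.75 and 1.12 FPKM. IGF2, of the insulin signalling list, was at 2138, 1914 and 290.7 FPKM. Some lists given above as standing apart in neither line did so under an alternative. Drug and steroid metabolism did so in sh#2 with a pseudocount of 0.1 and at a minimum mean of 5 FPKM. It also did so there under both scalings and by the mean of members. At that minimum, circadian clock genes stood apart in sh#7 and sh#2 (-0.52 and -0.36). Fatty acid and triglyceride synthesis genes did so too (0.15 and 0.12), and genes next to FTO in sh#2 (-0.30).

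Hepatocyte secreted protein genes were lower in sh#7. A trend in GC content and transcript length did not account for it, since the relative median was -1.10 once that trend was taken out. Replacement of Hep-G2 by other cells would lower hepatocyte transcription factors alike, but their median was -0.069 (bootstrap interval over genes -0.35 to 0.32). An effect of FTO knockdown may lower the list in sh#2 as well, where it was at -0.33, but with 1 line per shRNA it cannot be told apart from an off-target effect or drift of a line.

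Glycolysis and hypoxia genes were lower in both lines. With the trend in GC content and length taken out, the relative median was still -0.94 in sh#7 and -0.59 in sh#2. An unusual control library alone would leave the lines alike, but sh#7 lay below sh#2 by a relative median of -0.36. The part of the difference that both lines share may still come from the control culture, which 1 control library cannot settle. The density or oxygen of the cultures at harvest may also lower such genes together; 28 of the 29 members were below the median of all genes in both lines, and this cannot be told apart from an effect of FTO because the labels used here give neither.

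Neighbouring genes were lower together in sh#7. Against sh#2, 4 runs holding 238 genes passed the shuffle threshold of 0.35: NDRG2 to PRPF39 on chromosome 14 (99 genes, relative median -0.45), SNHG8 to HMGB2 (80 genes, -0.41) and C4orf41 to UFSP2 (11 genes, -0.40) on chromosome 4, and SDHD to C2CD2L on chromosome 11 (48 genes, -0.43), while sh#2 against control gave none, and sh#7 against control gave 3 shorter runs, of 23 and 33 genes on chromosome 14 and 12 genes on chromosome 4, and none on chromosome 11, where the 48 genes had a relative median of -0.21. Each run kept at least 91.6% of its median once the GC and length trend was taken out, and with runs called on every other gene, 89.5% of the 133 genes left out were lower (exact interval 83.0 to 94.1; these runs include 1 on chromosome 6 that the full set did not give), which argues against a few co-regulated genes. The highly and the weakly expressed genes left out had medians of -0.51 and -0.30, which is consistent with a lower copy number of these regions in part or all of the sh#7 cells, a hypothesis that DNA would have to test; a regional change of chromatin stays open. METTL3 and the fibrinogen genes lie within the chromosome 14 run and the longer chromosome 4 run, whose medians are far smaller than the fibrinogen differences.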
